A study of Mus musculus with 23 samples.

How the data were processed

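Single cells of mouse bone marrow were measured with CEL-seq in 23 libraries, 18 of cells from hand-dissected clumps and 5 of sorted HSC. Libraries were grouped by the cell subtype in the labels, and replicate numbers follow the order of the records, so they pair nothing. The labels name no animals, so p-values measure only the spread between libraries, which may be technical, and labels of sorted HSC replicates 2 to 5 share a stem, so these could be plates of one sort. Dissected libraries were sequenced on a NextSeq500 and sorted ones on a HiSeq2500 or NextSeq500, with no statement of which for each library, per the labels' protocols.

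Reads were aligned with BWA 0.6.2-r126 and the build was mm10, per the submitters' processing notes. The annotation, read filters and the steps from reads to the table are not given in the sources used here. The deposited table of the whole series holds estimated transcript counts (expected counts) for 23536 gene rows and 1915 cells. The values are not whole numbers because tags drawn more than once were corrected for, which was checked by converting them back to numbers of tags. The authors' per-library files hold estimated transcripts of the same kind (expected counts) per well of a dissected library, and were used as an alternative. Profiles of the 707 cells in both correlated at 0.979 or more, and cell totals in the table were, as the median of a library, 1.03 to 1.27 times those in the files, so the table is not a plain copy. The table has no spike-in rows. All of its cell columns were assigned to a library from their names. Of the libraries in the labels, dissected replicate 18 is not in the table and entered only an alternative with the per-library files, and sorted HSC replicate 2 was not analysed here. The design text calls a sorted sample a single cell, while the table holds 84 to 96 columns for each sorted library, and each column was taken as a cell.

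The number of the clump and of the cell within it were read from the column names, which the labels do not define; 525 of the 718 clumps so found held 2 cells. Cells with at least 1000 transcripts were kept. Doublets were not called, since each well received a cell by hand or sort, and an alternative left out the deepest 5% of cells per library. Dissected cells were scaled to equal totals and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 gave the clusters (scanpy 1.11.5, leidenalg 0.10.2, seed 1). Marker lists were fixed before the data were examined. The naming rule was set after the clusters had been seen: the list with most genes among the 10 leading genes by fold, at least 3 markers in 25% of the cells at 2-fold the level elsewhere, no other list with 2 or more leading genes, and, where no list led, 10 raised markers and at least 2 times those of the next list. That last number was raised after a cluster of muscle genes had taken the name mesenchymal and bone, which concerned alternatives only. The mixed cluster was clustered once more as an addition, and sorted HSC took no part in clustering.

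Transcripts were summed per library over kept cells and rounded to whole numbers. Differences were tested with edgeR 4.0.16 (TMM factors, filterByExpr, robust quasi-likelihood fit) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. This fit gives no SE of a log2 fold change. The SE printed with edgeR values is approximate: the size of the log2 fold change over the square root of the F statistic. Of 22 lists, those with at least 5 tested genes, 16 in all, were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and also with an estimated correlation and with fry. Classes were compared with sorted HSC where at least 3 libraries held 5 cells or more. Named genes were the 12 highest and 12 lowest log2 fold changes past the threshold with every sorted library on one side of the dissected median, 3 members of each list with the highest mean CPM, 5 highest and 5 lowest against the most frequent class outside its own markers, and genes of the sort and of stem cells, without predicted genes; 2 of the genes so chosen are not reported here. Positions come from GENCODE vM21 for 67 of 69 named genes, of which 4 matched by a newer name.

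Pairs of classes within a clump were counted per library and set against the mean of shuffled labels in that library. The difference was tested by flipping its sign over libraries, in full or with 100000 draws, and by 10000 shuffles pooled over libraries. Labels were shuffled over all kept cells of a library, and only over cells of clumps with 2 or more in an added alternative. For shares of cells with a transcript, each cell was also thinned to 1000 whole tags, which left out 26 dissected and 0 sorted cells. Intervals of shares are exact binomial, at 95%. A count of 0 was given a floor of 3 counts over the group. Intervals and floors cover counting error only.

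The gene test was tested on simulated counts with 50 genes changed by each of 4 folds. For sorted HSC against dissected libraries, with 3683 genes, it recovered 12% of genes changed 2-fold, 74% of those changed 4-fold, 90% of those changed 8-fold and 88% of those changed 16-fold, and 3 of 3504 unchanged genes were called. The test of pairs found the excess in 100% of 50 sets with a planted one that changed 50% of the mixed pairs, and smaller ones were not simulated. The test of successive wells gave a p under 0.05 in 0 of 20 sets with shuffled wells.

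Alternatives covered scaling (DESeq2 1.42.0 and library totals), gene filters, the minimum of transcripts per cell, depth, globin and artefact genes, per-cell means with limma-trend, per-library files, clustering, set tests, shuffles and leaving out each sorted library. No paired analysis was possible because nothing in the labels links a sorted to a dissected library.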

Results

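The series measured transcripts in single cells of mouse bone marrow with CEL-seq, a method that tags each captured mRNA molecule before amplification. Cells came from 2 groups. In 18 libraries, small structures of attached cells, here called clumps, were dissected by hand under a microscope and each cell was put in its own well. In 5 libraries, single haematopoietic stem cells (HSC) were sorted as lineage-negative, Kit-positive, Sca1-positive, CD150-positive and CD48-negative cells. The table of all cells held 17 of the dissected libraries and 4 of the sorted ones. Cells with at least 1000 transcripts were analysed. They numbered 707 of 1546 dissected wells, with 6 to 73 cells per library and a median of 2272 transcripts and 1049 genes per cell. They numbered 245 of 369 sorted wells, with 2 to 91 cells per library and a median of 1926 transcripts and 1168 genes. Summed over these cells, a library held 9032 to 313488 transcripts among the dissected and 3119 to 238770 among the sorted libraries. Sorted HSC replicate 1 held only 2 such cells, so 1 transcript in it stands for 322 CPM, the level of a gene scaled to a common library total.

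The first comparison asked which cell types made up the dissected clumps. Erythroblast-like cells, the haemoglobin-making precursors of red cells, had a mean share of 29.8% ± 18.9 (SD, n = 17 libraries), the highest of the named classes in this clustering. Stages of the neutrophil line followed. Myelocyte and metamyelocyte-like cells, marked by the granule genes Ngp, Camp and Ltf, made up 16.5% ± 13.05, myeloblast and promyelocyte-like cells, marked by the proteases Elane, Prtn3 and Ctsg and by myeloperoxidase (Mpo), 11.7% ± 6.62, and mature neutrophil-like cells, marked by Retnlg, Mmp8 and Mmp9, 5.75% ± 7.38. Eosinophil-like cells, marked by Prg2, Epx and Ear1, made up 6.55% ± 5.61, and macrophage-like cells, marked by C1qa, C1qb and Vcam1, 2.95% ± 4.24 (each n = 17). Pooled over cells, 245 of 707 cells were erythroblast-like, which is 34.7% with an exact 95% binomial interval from 31.1 to 38.3%. The erythroblast-like mean was 17.2% at a finer clustering, 19.2% with 1000 variable genes and 19.3% without the deepest 5% of cells. In the last of these, myelocyte and metamyelocyte-like cells had 24.8%. In each of these settings a cluster with Car1 and Minpp1 among its leading genes stayed unnamed, with 66, 61 and 68 cells in that order. In the clustering reported here these genes led an erythroblast-like cluster of 85 cells. The lower means therefore rest at least in part on the naming rule. No cluster took the name HSC and multipotent progenitor. Classes were clusters named by fixed marker genes, and libraries differed widely. A cluster of 57 cells, found only in micro-dissected replicates 1 to 5, had no leading genes of any list and stayed unnamed. The erythroblast-like share was 0 to 25% in these 5 libraries, of which replicate 5 had all of its 18 cells in the unnamed cluster, and 15.4 to 63.6% in the other 12. Of the erythroblast-like cells, 9 belonged to a group of 10 cells with 17742 CPM of a list of skeletal muscle genes.

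**Figure D1:**
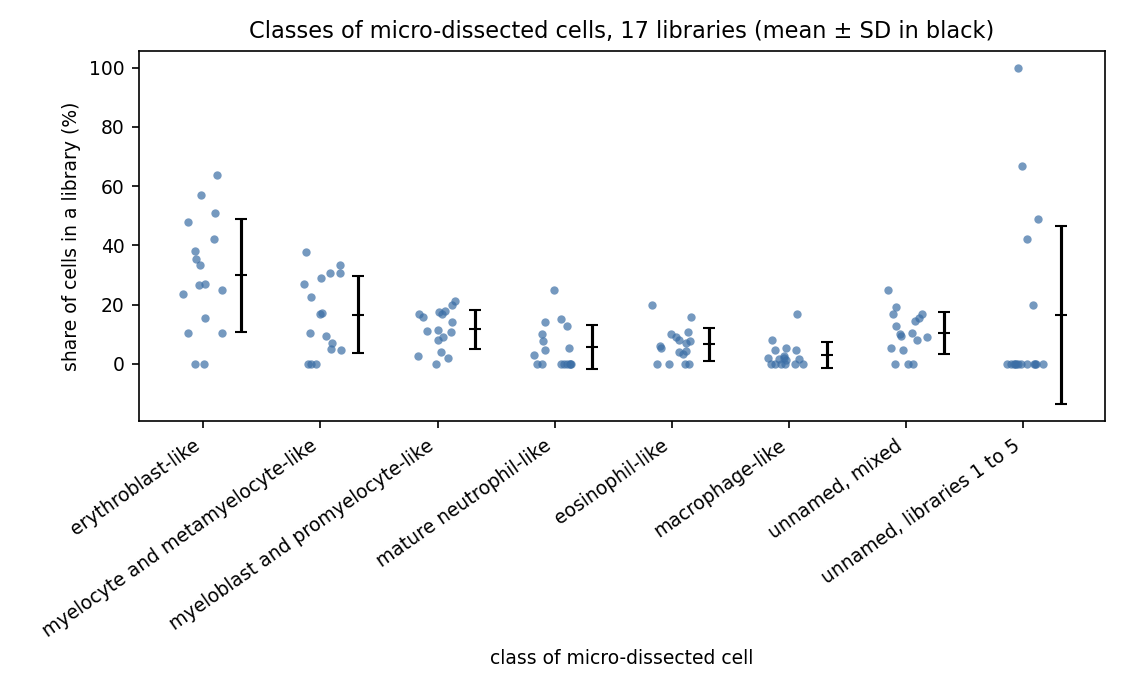
Each point is the share of cells of one micro-dissected library (percent, vertical axis) in a class (horizontal axis), with the mean and SD over 17 libraries in black. Erythroblast-like cells had the highest mean among named classes, 29.8%, and the unnamed cluster appeared in 5 libraries.

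Rarer cell types were found in a mixed cluster of 75 cells, which was clustered once more after its leading genes had been seen. It held 22 monocyte and dendritic-like cells, 18 B-cell-like cells, 17 megakaryocyte-like cells, 9 plasma-cell-like cells and 9 cells with basophil and lymphoid genes together that stayed unnamed. The monocyte and dendritic-like cells fell into 11 led by Irf8, Siglech and Bst2, genes of plasmacytoid dendritic cells, and 11 led by F13a1 and Ccr2, genes of monocytes. The megakaryocyte-like cells made up 2.40% of all cells (exact 95% interval 1.41 to 3.82%), of which 8 were led by Thbs1, Ppbp and Pf4 and had a median of 10272 transcripts, and 9 were led by Pf4 and had 3976. That share depends on the clustering: it was 1.13% at a finer one, 0.847% at a minimum of 500 transcripts and 11.2% at 2000. The plasma-cell-like cells, led by Igj, Txndc5 and Slpi, made up 1.27% (0.584 to 2.40%). Their share was also 1.27% at a finer clustering, but 10.7% at 2000 transcripts, where the leading genes of the cluster included Fcnb and Camp. The monocyte and dendritic-like share was 3.11% here, 3.68% at a finer clustering, 7.63% at a minimum of 500 transcripts and 7.36% with 1000 variable genes.

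The second comparison asked which cell types were attached to each other. The column names gave 440 clumps with a cell that passed the minimum, of which 214 held at least 2 such cells and gave 329 pairs. Erythroblast-like cells shared a clump with one another in 70 pairs, against 49.5 when class labels were shuffled within each library, a ratio of 1.41, with an excess in 11 of 14 libraries. Erythroblast-like cells shared a clump with myelocyte and metamyelocyte-like cells in 33 pairs against 48.3, a ratio of 0.684, with a deficit in 12 of 13 libraries. Both pairs passed the sign-flip permutation test over libraries, 2-sided, each with a Benjamini-Hochberg adjusted p of 0.0273 over 21 class pairs (unadjusted p = 0.00296 and 0.00189). Mature neutrophil-like cells shared no pair with myeloblast and promyelocyte-like cells, where 5.92 were expected. Of the 3 calls of the sign-flip test this was the last, but with 0 pairs observed its exact p of 0.00391 is set by the number of libraries, 9, and the pooled shuffles gave an adjusted p of 0.0525.

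Other pairs missed the threshold of the sign-flip test. Erythroblast-like and mature neutrophil-like cells shared 6 pairs against 18.3 (adjusted p = 0.0615, sign-flip permutation test, a deficit in 8 of 9 libraries). Erythroblast-like and myeloblast and promyelocyte-like cells shared 42 against 29.2 (adjusted p = 0.53, permutation test, an excess in 6 of 14 libraries). Erythroblast-like and macrophage-like cells, which form islands around a central macrophage in marrow, shared 11 against 6.73 (adjusted p = 0.53, permutation test, an excess in 5 of 10 libraries). With shuffles pooled over libraries in place of the sign-flip test, 5 pairs passed: the first 2 above, the first 2 of this paragraph, and mature neutrophil-like cells with one another, 9 against 3.63. The sign-flip test was loose for rare pairs, since 41.5% of 200 sets of shuffled labels gave at least 1 pair past the adjusted threshold, while unadjusted p fell below 0.05 in 3% of sets for the erythroblast-like pairs and 1.5% for the erythroblast-like and myelocyte-like pairs. All 3 calls were lost at a finer clustering and with the globin genes taken out before clustering, where the erythroblast-like ratio was 1.90 (adjusted p = 0.172, permutation test) and 1.48 (adjusted p = 0.0547). At a minimum of 2000 transcripts per cell the erythroblast-like ratio was 1.11 and that of mature neutrophil-like with promyelocyte-like cells turned to 1.24 (each adjusted p = 1, sign-flip permutation test), while no cluster took the name myelocyte and metamyelocyte, so its pairs were not tested. The cluster named mature neutrophil at 2000 transcripts raised 9 markers of the myelocyte and metamyelocyte list against 6 of its own. The ratio of 1.24 therefore does not concern the same class and is no reversal of the main result. The call with myelocyte-like cells was also lost without the cells with muscle genes, with the ratio at 0.691 (adjusted p = 0.0542, permutation test).

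**Figure D2:**
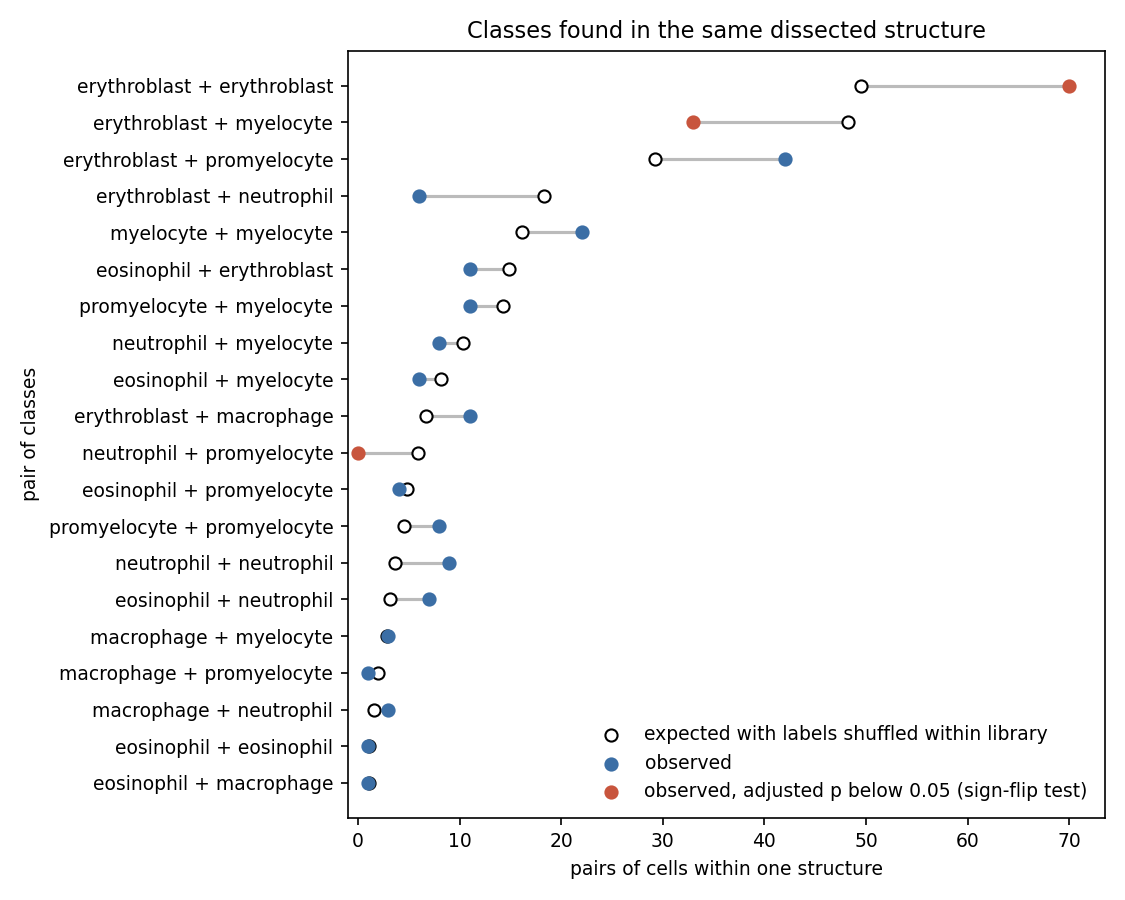
Each line is a pair of classes with at least 1 expected pair, the horizontal axis is the number of cell pairs within one clump, open points are the numbers expected with labels shuffled within library and filled points the numbers observed. Erythroblast-like cells lie above expectation with one another, 70 against 49.5, and below it with myelocyte-like cells, 33 against 48.3.

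Sorted cells have no clump, so their likeness between wells with successive numbers was set beside that of dissected cells. A library of a single sorted population leaves little room for successive wells to exceed other pairs, while dissected libraries mix classes. The sorted value is therefore not a like baseline, and the comparison cannot decide how alike successive wells are without clumps. The correlation of the profiles of cells in successive wells exceeded that of other pairs of the same library by 0.0173 ± 0.0169 (SD, n = 15 libraries) in dissected cells and by 0.00173 ± 0.00304 (n = 3) in sorted cells. The difference did not pass an exact permutation test over libraries (2-sided p = 0.142, all 816 splits). Among dissected cells in wells 12 apart, the excess was 0.0426 ± 0.0475 for cells of one clump and 0.003 ± 0.0276 for cells of different clumps (each n = 15). Of the 367 dissected pairs at that distance, 192 were of one clump, so the test of successive wells left these out. Over all pairs 12 apart, the excess was 0.0261 ± 0.0318 in dissected and 0.00158 ± 0.00105 (n = 3) in sorted cells (exact permutation test, p = 0.214).

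The third comparison set the sorted stem cells against the dissected cells. Among genes that passed the expression filter and the test, with every sorted library on one side of the dissected median, the highest log2 fold changes in sorted HSC were those of Ifitm1, an interferon-induced membrane protein (log2 fold change 6.12 ± 0.47 SE), Hlf, a transcription factor of stem cells (5.96 ± 0.39), Gpr56, an adhesion receptor (4.39 ± 0.49), Gimap6 (4.13 ± 0.50), Eltd1 (4.09 ± 0.40), Mfng, a glycosyltransferase that modifies Notch (3.72 ± 0.41), Gcnt2 (3.64 ± 0.36), Cd34, a surface protein of progenitors (3.57 ± 0.60), Dusp2 (3.47 ± 0.56), Ptprcap (3.40 ± 0.48), Erdr1 (3.21 ± 0.33) and Ifi203 (3.13 ± 0.51). The choice of these 12 genes rests partly on sorted HSC replicate 1 with its 2 cells. Cd34, Eltd1, Mfng and Ifi203 each stood at 322 CPM in it, the level of 1 transcript. Dusp2 stood at 966 CPM in it against 85.5 to 167 in the other sorted libraries, and Gimap6 at 1289 against 178 to 308. Genes with no transcript in those 2 cells could not be listed as higher. The lowest were genes of mature blood cells. Of the eosinophil granule genes, Prg2 was at least 1103-fold lower, Ear1 at least 357-fold and Ear6 at least 228-fold. Of neutrophil genes, Lcn2, an iron-siderophore binding protein, was at least 826-fold lower, Ltf (lactoferrin) 539-fold and Elane (neutrophil elastase) 281-fold. Ly6c2, of the monocyte and dendritic list, was at least 324-fold lower, and of globins Hbb-b1 was at least 270-fold lower. These genes had no transcript in sorted cells, so the bounds set 3 counts over the whole group. S100a9 was lower by a ratio of 4808 (counting interval 1645 to 23313), Camp by 5935 (1065 to 234433) and Ngp by 3210 (889 to 26507). S100a8 had 4 sorted transcripts and a log2 fold change of -11.71 ± 0.72.

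In all, 1106 of 3639 genes passed edgeR's quasi-likelihood test at an adjusted p of 0.05, 408 higher and 698 lower in sorted HSC (4 against 17 libraries). The higher calls numbered 693 without sorted HSC replicate 1 and 268 without replicate 3. Adjusted p ranged from 6.9e-15 for S100a8 to 0.00748 for Prg2 among the genes named above. Of the 1106, 73 had no transcript in sorted cells and 75 had 1 to 3. The split rests on scaling: with library totals in place of TMM factors, the median log2 fold change of all genes moved from -0.16 to 0.17 and the higher calls from 36.9 to 57.5% of 1312. The groups also differ in how cells were collected and partly in the sequencer, and neither can be separated from the cell type.

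Genome positions on mm10 place Ifitm1 on chromosome 7 from 140967221 to 140969825, Hlf on chromosome 11 from 90336536 to 90390895, Gpr56 (now Adgrg1) on chromosome 8 from 94974751 to 95014217 and Cd34 on chromosome 1 from 194938819 to 194961279. S100a8 and S100a9 are neighbours on chromosome 3, from 90668978 to 90670035 and from 90692632 to 90695721. Prg2 lies on chromosome 2 from 84980461 to 84983632 and Lcn2 on chromosome 2 from 32384633 to 32388252. Reads of Ear1 and Ear6, of the globins and of Ifi203 can be shared with near-identical copies, and Erdr1 and Hbb-b1 were not placed in the annotation used, so their values are uncertain.

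Several genes of the sort or of stem cells differed between the groups. Kit, the stem cell factor receptor, was higher in sorted HSC (log2 fold change 2.91 ± 0.43, adjusted p = 4.6e-06, edgeR), as was Ly6a, which encodes Sca1 (2.44 ± 0.62, adjusted p = 0.00469). Kit lay above the dissected median in 3 of 4 sorted libraries and Ly6a in 4 of 4. Cd48, with 3 sorted transcripts, was lower by a ratio of 12.4 with a counting interval from 4.17 to 60.7 (adjusted p = 1.1e-04, edgeR). Procr, the endothelial protein C receptor, had 57 transcripts in sorted and 0 in dissected cells, at least 87.4-fold higher over the group. Mecom, a transcription factor of stem cells, had 65 and 0, at least 99.6-fold higher. Slamf1, which encodes CD150, had levels of 31.4 ± 29.1 CPM (SD, n = 4) in sorted and 25.7 ± 57.01 CPM (n = 17) in dissected libraries. These 3 genes were too rare for the test.

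Of the lists of cell-type markers, the HSC and multipotent progenitor list was higher in sorted HSC, with 9 of 12 tested members higher and none lower (11 of 12 adjusted over the list alone), including Hlf, Txnip, a regulator of glucose uptake (2.73 ± 0.34), and Ly6a. Lists of every neutrophil stage were lower: 8 of 10 promyelocyte members (8 adjusted over the list alone), among them Mpo, lower by a ratio of 782 (140 to 30877), and Prtn3 (-3.16 ± 0.74); all 10 myelocyte members (10); and 7 of 8 mature neutrophil members (7), among them Retnlg (ratio 257, 87.8 to 1246). The erythroblast list was lower in 18 of 19 members (19 adjusted over the list alone), from the anion exchanger Slc4a1 (ratio 643, 115 to 25423) to carbonic anhydrase Car2 (-1.54 ± 0.52). The eosinophil list was lower in 6 of 6 members (6 adjusted over the list alone, list adjusted p = 0.261 with an estimated correlation). The monocyte and dendritic list was lower in 6 of 11 members (7 past the threshold adjusted over the list alone, of which 1 was higher, list adjusted p = 0.261 with an estimated correlation), among them lysozyme Lyz2 (-3.54 ± 0.75) and the lysosomal protein Psap (-1.39 ± 0.44). The macrophage list was lower in 6 of 10 (8 adjusted over the list alone, list adjusted p = 0.387 with an estimated correlation), among them Vcam1, at least 48.9-fold lower, and Hmox1, which degrades haem (-3.24 ± 1.22), while Apoe had a value of 0.52 ± 0.84 (adjusted p = 0.686).

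Among lists of cell programmes, ribosomal protein genes were higher in sorted HSC, with 14 of 27 members higher and none lower (15 adjusted over the list alone, list adjusted p = 0.261 with an estimated correlation), such as Rplp1 (0.87 ± 0.28), while Rpl4 had -0.38 ± 0.34 and Rplp0 0.39 ± 0.32 and did not pass. Of the list of MHC class I and interferon response genes, 4 of 11 were higher and 1 lower (8 and 2 adjusted over the list alone, list adjusted p = 0.22 with an estimated correlation), with H2-K1 at 2.24 ± 0.31, and B2m at 0.69 ± 0.31 (adjusted p = 0.0877) and H2-D1 at 0.70 ± 0.34 (adjusted p = 0.113) short of the threshold. Cycling genes were lower in 19 of 27 members and higher in none (19 adjusted over the list alone, list adjusted p = 0.088 with an estimated correlation), among them the chromatin protein Hmgb2 (-2.46 ± 0.41) and topoisomerase Top2a (-2.52 ± 0.43), while Tubb5 had -0.48 ± 0.32. Of the list of adhesion and niche signalling genes, 8 of 15 were lower (9 adjusted over the list alone, list adjusted p = 0.19 with an estimated correlation), among them the integrin Itgb2 (-4.47 ± 0.54), while Cd47 had -0.66 ± 0.33 and Cxcr2 -0.60 ± 0.45.

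These 12 lists passed limma's camera test among 16 tested with a preset correlation of 0.01, with adjusted p from 1.5e-19 for the myelocyte list to 0.0145 for the monocyte and dendritic list. Other splits of the 21 libraries gave a median of 6 lists past the threshold with the preset correlation, so passing it is weak evidence for a list. With an estimated correlation, 5 held: HSC and multipotent progenitor, promyelocyte, myelocyte, mature neutrophil and erythroblast.

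The other 4 lists did not pass camera, while limma's fry, which does not compare a list with other genes, called 15 of the 16 lists, all but the megakaryocyte list. Of the megakaryocyte list, 1 of 17 members was lower (none adjusted over the list alone). The log2 fold change was below 0 in 16 of the 17, with a median of -2.67 and a mean of -3.05. Camera, which sets the mean test statistic of the list against that of other genes, pointed up (adjusted p = 0.852). Ppbp had 3 sorted transcripts and a ratio of 329 (113 to 1598), Thbs1 a log2 fold change of -6.30 ± 2.75 and Pf4, platelet factor 4, -1.83 ± 1.59, none past the threshold, and the list's level ranged from 81.3 to 31238 CPM among dissected libraries. Of the plasma cell list, 3 of 7 were lower (3 adjusted over the list alone, list adjusted p = 0.203), with Slpi lower by a ratio of 217 (38.8 to 8572), Sec11c at -1.18 ± 0.38 and Igj, with 0 sorted and 2533 dissected transcripts, short of the threshold (adjusted p = 0.0815). Of the dissociation stress list, 6 of 15 were lower (6 adjusted over the list alone, list adjusted p = 0.212, and 0.0208 without sorted HSC replicate 1), with Klf6 at -1.81 ± 0.58, Hspa8 at 0.55 ± 0.32 and Hsp90aa1 at -0.16 ± 0.37. Its summed level was nonetheless 4235 ± 1921 CPM in sorted (SD, n = 4) and 3477 ± 951 CPM in dissected libraries (n = 17). Sorted HSC replicate 1 held 7112 CPM and the other sorted libraries 2918 to 3553. Of the list of quiescence and HSC retention, 1 of 8 was higher and 3 lower (2 and 4 adjusted over the list alone, list adjusted p = 0.524), with Gfi1, a transcriptional repressor, at -1.72 ± 0.57 and Cxcr4 at -1.21 ± 0.50 (adjusted p = 0.0611).

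**Figure D3:**
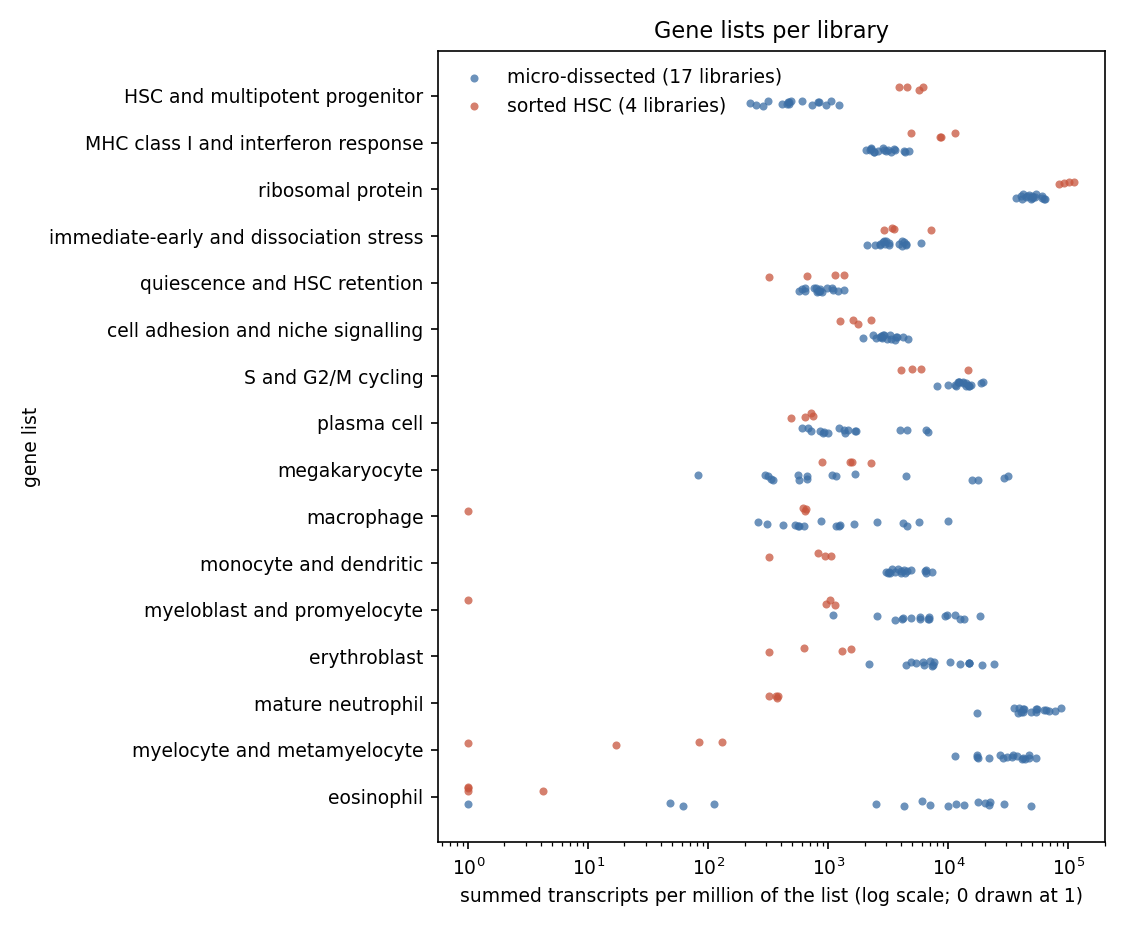
Each point is the summed level of a gene list in one library, in CPM on a log axis with 0 drawn at 1, for 17 micro-dissected and 4 sorted libraries. The HSC list lies at 5058 CPM on average in sorted and 590 in dissected libraries, and lists of mature blood cells lie lower in sorted libraries.

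The fourth comparison set the sorted stem cells against single classes of dissected cells. Against erythroblast-like cells in 11 libraries, 773 of 1548 genes passed edgeR's test, 350 higher and 423 lower in sorted HSC. Without sorted HSC replicate 3 these were 199 and 419. Ifitm1, with 767 sorted transcripts and 0 in the class, was at least 338-fold higher, Hlf at least 161-fold, Gcnt2 at least 70.5-fold and Eltd1 at least 50.2-fold, and Ptprcap was higher by a ratio of 231 (counting interval 63.3 to 1911). The beta globin Beta-s had a log2 fold change of -10.03 ± 0.70. It was among the leading genes of an erythroblast-like cluster. Classes were formed from these same transcripts, so the levels of such genes in a class were partly set by that choice. Rhd, of the Rhesus blood group, was at least 233-fold lower and the claudin Cldn13 at least 116-fold. Prg2 (at least 92.1-fold lower) and S100a9 (ratio 499, 171 to 2423), genes of granulocytes, had 365 and 1979 transcripts in the sums of erythroblast-like cells. Sorted HSC differed from myelocyte and metamyelocyte-like cells in 548 of 779 genes (10 libraries), from myeloblast and promyelocyte-like cells in 526 of 1149 (7 libraries), from mature neutrophil-like cells in 224 of 252 (5 libraries) and from eosinophil-like cells in 226 of 519 (3 libraries). No library held the minimum of 5 macrophage-like cells. With library totals in place of TMM factors, the higher calls moved from 43.8 to 58.4% for the eosinophil class and from 49.6 to 59.3% for the myelocyte class. The eosinophil count moved to 393 without sorted HSC replicate 1, 107 without replicate 3, 46 higher and 80 lower without replicate 4, and 123 without replicate 5.

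The last part described variation among sorted HSC. Their libraries differed in the share of cells with a transcript of genes of the sort or of stem cells. Kit was seen in 70.3% of cells of replicate 3, 27.8% of replicate 4 and 78.8% of replicate 5, Procr in 28.6, 20.8 and 7.5%, Mecom in 28.6, 13.9 and 22.5%, Slamf1 in 11, 2.78 and 11.2% and Ly6a in 47.3, 43.1 and 37.5%. Replicate 1 had 2 cells, of which 1 held Ly6a. With every cell thinned to 1000 transcripts, Kit was seen in 42.9, 16.7 and 63.8% of replicates 3, 4 and 5. Pooled over sorted HSC, Kit was seen in 60% of cells (exact 95% interval 53.6 to 66.2%, median 1926 transcripts) against 3.67% of erythroblast-like cells (1.69 to 6.86%, median 1822 transcripts). Erythroblast-like cells held Ly6a in 3.67%, Slamf1 in 0.816%, and Mecom and Procr in 0 of 245 cells, which limits the share of cells with a transcript to 1.49% (exact interval), not the share that expresses the gene. Cd48 was seen in 2 of 245 sorted cells, at or below its level of 1.63% in erythroblast-like cells. Cycling genes summed to 7372 ± 4867 CPM (SD, n = 4) in sorted HSC, of which replicate 1 with its 2 cells held 14588 and the others 4062 to 5879, against 13522 ± 2791 in dissected libraries (n = 17). Genes of the megakaryocyte list summed to 1558 ± 560 CPM (n = 4), from 882 in replicate 3 to 2252 in replicate 1, against 6231 ± 10455 in dissected libraries (n = 17).

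**Figure D4:**
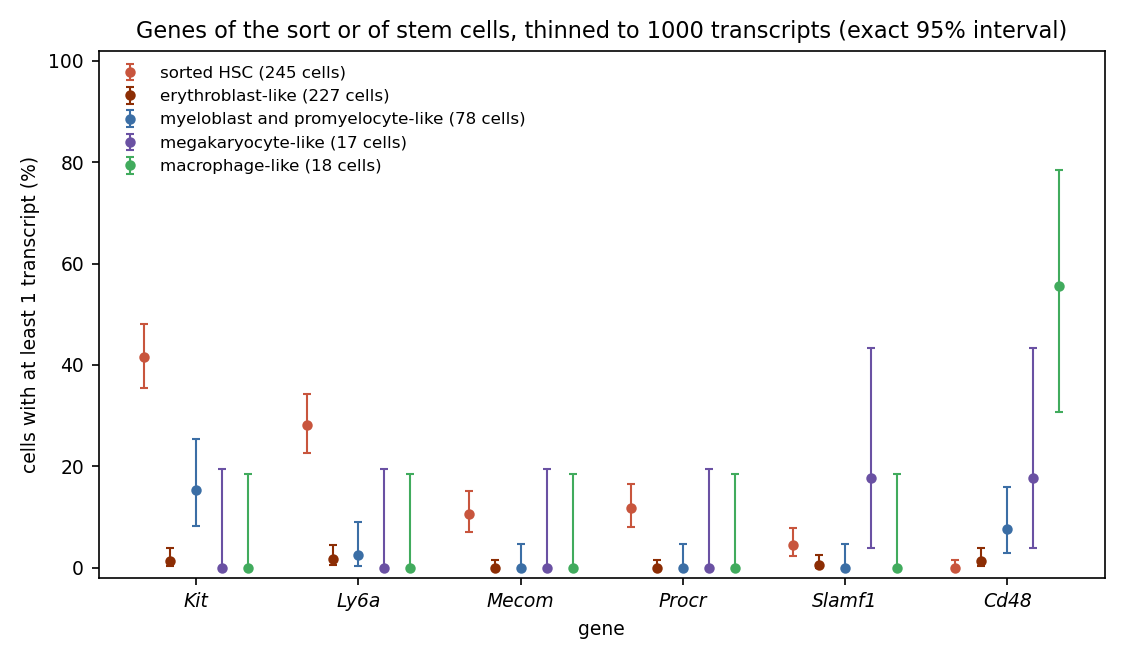
The vertical axis is the percentage of cells with at least 1 transcript of each gene on the horizontal axis after thinning to 1000 transcripts, with exact 95% intervals, for sorted HSC pooled over libraries and 4 classes of dissected cells. Kit was seen in 41.6% of sorted HSC and 15.4% of myeloblast and promyelocyte-like cells, and Mecom and Procr in none of the dissected cells drawn, of which megakaryocyte-like and macrophage-like cells number 17 and 18.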

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

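The search for a library far from the others covered 85 values in the 4 sorted HSC libraries and found 17, where chance alone gives about 1 in 20. That rate does not hold where the other 3 libraries share a value, as for the 8 values of replicate 3 and the 1 of replicate 4, and share and level of a list count as 2 values. None of these results had a planned test of its own.

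In replicate 1, which holds 2 cells, 8 values stood apart. It had 0 CPM of the myeloblast and promyelocyte list, and 0% of cells and 0 CPM for both the macrophage and the endothelial list. It had 7112 CPM of the stress list, 966 CPM of Dusp2 and 1289 CPM of Gimap6. In this library 1 transcript stands for 322 CPM.

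In replicate 3, the deepest sorted library, 8 values stood above the others. The eosinophil list was seen in 1.1% of its cells at 4.20 CPM, and Cd48 in 2.20% of its cells at 12.6 CPM. Its levels were 4.19 CPM for Camp, 8.39 for Ngp, 16.8 for S100a8 and 12.6 for S100a9. In replicate 4, the HSC and multipotent progenitor list was seen in 98.6% of cells, against 100% in the others.

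Micro-dissected replicate 18 has its own file and no column in the table, so only an alternative of the gene comparison used it. Of 16 cell-type lists, 11 were above every sorted HSC library there. The mature neutrophil list stood at 34748 CPM and the myelocyte and metamyelocyte list at 22282 CPM, near the medians of the other dissected libraries, 35005 and 26482 CPM. The mesenchymal and bone list stood at 4502 CPM. For this list the highest of the other dissected libraries was 1050 CPM. Its leading genes there were the bone and skin collagens Col1a2 (1698 CPM, at most 284 in the other dissected libraries) and Col1a1 (902 CPM, at most 60.2) and the matrix protein decorin, Dcn (645 CPM, at most 68.8).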

How the results depend on the processing

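Some alternatives were added after the data were seen: libraries without the 5 of the unnamed cluster, only libraries as deep as the 3 deepest sorted ones, the file of 1 more library, globins or muscle cells left out of the pairs, wells 12 apart, and shuffles on each side of a library's median depth or within clumps of 2 or more. Of 1703 values under alternatives, 1573 kept their side of the threshold or stayed within 1.5 times or 1 SD. These include values that changed direction with no call on either side, such as that of the megakaryocyte list. Of the rest, 57 lost and 43 gained a call, 29 moved and 1 changed direction with a call in at least 1 of the settings. A planned minimum of 10 cells per class left too few libraries for the eosinophil and mature neutrophil classes, and wells 2 apart did not apply to pairs since clumps were known. All 47 values of the 6 class shares stayed within 1 SD, which is wide: the erythroblast-like mean of 29.8% went down to 17.2% and its pooled share from 34.7 to 21.5% at resolution 2.0. At that resolution 66 cells led by Car1, a leading gene of an erythroblast-like cluster in the main setting, stayed unnamed. At 2000 transcripts no cluster was named myelocyte and metamyelocyte, so that share and its pairs have no value there. The 5 values of successive wells kept their side. Of 1076 values of named genes against dissected cells, 39 lost and 32 gained a call and none with a call changed sign, while over all genes per-cell means with limma-trend called 509 of the 1106 and gave 38 the other sign; all 78 against the erythroblast class kept theirs.

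The count of 1106 genes became 2838 with no filter, 584 at a minimum of 2000 transcripts, 20 of 53 tested with every library thinned to 3104 transcripts, and 1869 among the deepest libraries. Filters and thinning change how many genes can be tested, and for the other shifts the cause was not tested. Leaving out a sorted library gave 743 to 1454 genes, and 107 to 393 for the eosinophil class. The erythroblast class gave 429 genes at Leiden resolution 2.0, where fewer genes were tested. Lists past the threshold fell from 12 to 5 with an estimated correlation.

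The 3 class pairs became 5 with pooled shuffles, 6 with pooled shuffles on each side of the median depth and 5 at resolution 0.5. They became 0 in the sign-flip test at resolution 2.0 (5 of 55 at an unadjusted p under 0.05), at 2000 transcripts (5 of 28) and with globins out (4 of 28). For erythroblast-like pairs, observed over expected was 1.90 at resolution 2.0 (adjusted p = 0.172, permutation test), 1.11 at 2000 transcripts and 1.48 with globins out (adjusted p = 0.0547, over 28 pairs in place of 21). For erythroblast-like with myelocyte-like cells it was 0.827 at resolution 2.0, 0.754 with globins out and 0.691 without muscle cells (adjusted p = 0.0542). Mature neutrophil-like and promyelocyte-like cells stayed at 0 pairs but lost the call with pooled shuffles, at resolution 2.0, with globins out, within clumps of 2 or more and without the 5 libraries. At 2000 transcripts the ratio was 1.24, but the cluster named mature neutrophil there raised 9 myelocyte and metamyelocyte markers against 6 of its own. That value does not concern the same class. For the lost calls the cause was not tested. Depth limits which genes can be tested, 53 when all libraries had that of the shallowest.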

Other observations

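Tests of the erythroblast-like pairs, of pairs in the divided mixed cluster and in successive wells, and the counts of other splits were chosen after the results were seen; those of the unnamed cluster, the muscle genes and the erythroblast clusters were written before theirs.

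The rarer classes also met in clumps. With the mixed cluster divided, megakaryocyte-like cells shared 3 clump pairs with monocyte and dendritic-like cells against 0.409 by shuffling (pooled permutation p = 0.0077, adjusted p = 0.0852 over 55 pairs). They shared 1 pair with erythroblast-like cells against 4.36 (pooled permutation test, adjusted p = 0.519). Outside clumps, mature neutrophil-like and myelocyte-like cells sat in successive wells 19 times against 6.88, in 9 of 9 libraries (exact sign-flip p = 0.00391, adjusted p = 0.082). Genes of the endothelial list, too rare for the test, summed to 365 ± 244 CPM in sorted HSC (SD, n = 4) and 77.3 ± 50.4 CPM in dissected libraries (n = 17). Ly6a, the gene of the stem cell marker Sca1, was seen in 8 of 9 plasma-cell-like cells, at 3094 CPM against 330 CPM in sorted HSC.

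Erythroblast-like cells shared clumps with one another at 1.41 times expectation. Against carry-over between wells 12 apart as the cause, the ratio was 0.777 in such wells that held different clumps (0.951 in wells 1 apart), and against shared depth the excess stayed at 1.41 with an adjusted p of 0.00525 when labels were shuffled among cells of like depth (pooled permutation test). Against globin RNA from a neighbour as the whole cause, the ratio was 1.48 with globin genes out, although the call then ended over more class pairs. Scale also stays open. Pairs from different clumps of one larger structure were also above expectation (200 against 162, pooled permutation p = 0.0025, but adjusted p = 0.246 in the sign-flip test). Erythroblast-like cells may therefore lie together beyond the dissected clump. Cells of one clump may also share a stage: 37 erythroblast-like pairs came from one of the 3 erythroblast clusters against 25.8 by shuffling (permutation p = 0.0057).

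The unnamed cluster of 57 cells was found in dissected replicates 1 to 5 and was led by B630005N14Rik, Gna11 and 5830416I19Rik. Background transcripts of these libraries are a candidate explanation. In their 264 wells under 500 transcripts the 10 leading genes reached 52516 CPM, which is 335% of their level in the cluster, against 192 CPM in such wells of the other libraries. In cells of named classes from the same libraries these genes were 22.9-fold higher than in the same classes elsewhere. Both background and a difference between libraries in all their cells therefore stay open, and no biological explanation was tested.

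At Leiden resolution 2.0, 10 cells from 10 clumps in 5 libraries were led by skeletal muscle genes such as Acta1 (16734 CPM against 65.4 in other cells) and Tnnt3 (11227 against 48.2). A list of 15 other muscle genes, written after the leading genes were seen, stood at 17742 CPM in them and 39 CPM in sorted HSC. Free RNA spread over the libraries is argued against, since other cells of the same libraries held 0.474% of that level, while carry-over from a neighbouring well stays open, since 22 neighbouring wells held 1.35%, between the bounds set for it. In the classes reported, 9 of these cells counted as erythroblast-like, and the 10 held 36010 CPM of erythroblast genes against 116454 in the rest of that class and 7310 in mature neutrophil-like cells. Fragments of muscle fibre picked up with marrow may be their source, which was not tested, and no gate would have removed them.

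In 100 of the 5985 splits of the 21 libraries, only the real one gave as many as 1106 genes, and the highest of the others gave 42. A random grouping of these libraries would thus seldom give that count. The splits treat libraries as independent, while sorted ones could be plates of one sort. They also cannot separate cell type from how cells were collected. For the 12 gene lists, 7 of 100 splits gave as many. The median of the others was 6 lists and the highest 14, so chance cannot be excluded for the count of lists. For the classes the real split alone reached its count: 773 genes for the erythroblast class against 658 in the highest of the others, 548 against 9 for the myelocyte, 526 against 169 for the promyelocyte and 224 against 158 for the mature neutrophil class, each in 100 splits, and 226 against 177 for the eosinophil class in all 35 splits. The highest other splits for the erythroblast, promyelocyte and myelocyte classes kept 3 sorted libraries together. That of the eosinophil class also left 3 together, on the other side, and that of the mature neutrophil class left all sorted libraries together there. Each of these splits was therefore close to the real one.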
